A study of Mus musculus with 6 samples.

How the data were processed

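RNA from the livers of 6 male C57BL/6 mice was measured on an Affymetrix mouse exon array, summarised to 1 value per probe set. Here a probe set is 1 row of the deposited values. Most named genes had 1 such row, so it is not an exon-level value. Per the labels, 3 mice carried floxed Cpt2 alleles together with a Cre recombinase driven by the albumin promoter, which is active in hepatocytes, and 3 controls carried the floxed alleles alone. All mice had been fasted for 24 hours. RNA was extracted with Trizol and a column cleanup, and labelled with biotin.

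The deposited values are on the log2 scale. Partek, RMA and the mouse build mm9 are named for them, without versions, per the submitters' processing notes. RMA as a method subtracts background, sets the arrays to a common distribution and summarises probes on the log2 scale. Which options were used is not given in the sources used here. The values of 115050 probe sets ran from 0.668 to 13.6, with a median of 2.88. RMA compresses changes of dim probe sets towards 0, and a probe set averages over probes along a gene, so that loss of part of a transcript is understated. Scanner files and detection calls were not used here, so no level is called above or below background. The number of arrays limits the precision, with 3 per group.

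Genes were named from the platform annotation. Of the probe sets, 25469 named 1 gene, 2286 named several and 87295 named none in that table. Entrez identifiers of 24878 of the probe sets with 1 gene (97.7%) were matched to a RefSeq gene table of another build, GRCm38, which was used for names only and changed 0 symbols. No coordinates are given for this reason. Probe sets with 1 gene covered 20242 genes. For the 3084 genes with several, the probe set with the highest mean over all 6 arrays stood for the gene. Probe sets naming several genes or none were left out of the gene counts. All 6 columns of the table were used.

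Differences between knockout and control were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate, no filter on dim genes and no minimum fold). P-values were adjusted by the Benjamini-Hochberg method over the 20242 genes, with a threshold of 0.05. The moderated test had 4 residual and 4.23 prior degrees of freedom. A further count took a log2 fold change of at least 1 as well. Errors given as SE are those of the moderated test, and errors given as SD are between the 3 arrays of a group. Intervals given for the median of a list come from the ranked values of its genes. They show the spread among genes of the same 6 mice, not between mice.

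Before the data were examined, the tests, the alternatives, 40 gene lists with 740 members and the rule for the genes named in the text were fixed. Of the members, 605 were measured by a probe set of their own. Lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 39 lists tested. The estimated correlation of each list and the rotation test fry were alternatives. The rule named Cpt2, then the 12 largest increases and 12 largest decreases among genes past adjusted p 0.05 whose groups did not overlap. Predicted genes, olfactory and vomeronasal receptors and small RNA genes were left out of these 24. In each list it named up to 4 members past adjusted p 0.05 with the largest absolute change, or, where none passed, the member with the largest change by its values. Gene families by symbol, the lists of lysosomal genes, decay factors and ribosomal protein genes, and fry and the estimated correlation with listed age as a covariate for 3 lists, were added after the data were seen.

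The labels list ages rising by 1 week from sample to sample, from 9 to 14 weeks, with controls at the younger and knockouts at the older end. The growth protocol in the same labels gives 9 weeks for all mice. A slope on listed age within genotype was therefore tested in the same model, and listed age as a covariate was an alternative. Within each genotype listed age rises with the replicate number, so both fits are equally fits on sample order. Further alternatives were quantile normalization, centring of arrays on their medians, 2 filters on dim genes, the mean of all probe sets of a gene, every probe set tested separately, a mean-variance trend with robust prior, unmoderated statistics, array weights, replicate number as a block, and leaving out each array in turn.

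The gene test was run on simulated data with the same genes, means and residual spreads, in which 200 of 20242 genes were changed. It recovered 14 of 67 genes changed by 0.5 on the log2 scale (20.9%), 60 of 67 changed by 1 (89.6%) and 61 of 66 changed by 2 (92.4%). The direction was wrong for 0 of them, and 5 of 20042 unchanged genes were called. On simulated lists, the camera tests and fry each recovered 10 of 10 lists shifted by 0.5, with 1 false call among 190 unshifted lists for camera with the preset correlation and 0 for the others. The simulated genes were drawn independently. Real lists can be correlated, with an estimate of 0.446 for peroxisomal fatty acid oxidation, so these false call counts do not carry over to them.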

Results

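Liver gene expression was measured in 3 mice lacking Cpt2 in hepatocytes and 3 floxed controls, all male and all fasted for 24 hours. Cpt2 encodes carnitine palmitoyltransferase II, the enzyme of the inner mitochondrial membrane that turns imported acylcarnitines back into acyl-CoA for beta-oxidation. Each mouse gave 1 array, and the labels call the samples biological replicates. Over 20242 genes, arrays correlated at r = 0.988 to 0.989 among controls, 0.985 to 0.987 among knockouts and 0.969 to 0.977 between the genotypes. The first principal component, which separated the genotypes, held 50.9% of the variance. The comparison asks how loss of Cpt2 in hepatocytes changes liver gene expression during a fast.

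Cpt2 itself was lower in each knockout liver than in each control liver. Its log2 values were 7.56, 7.72 and 7.63 in the controls and 6.48, 6.73 and 6.75 in the knockouts. The mean fell by 0.99 on the log2 scale (SE 0.11, adjusted p = 0.0013 by limma), leaving 50.5% of the control signal. The gene had 1 probe set, which averages over the transcript, and the deletion is limited to hepatocytes, so the remaining signal does not measure the transcript left in hepatocytes. The deleted exons are not given in the sources used here. The adjusted p was 0.0692 where all 115050 probe sets were tested together and 0.0753 with listed age as a covariate, against 0.000508 to 0.0327 in the other 15 alternatives.

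The largest increase in the knockout livers was that of Pdk4, the kinase that switches off pyruvate dehydrogenase, which rose 30.5-fold from a log2 value of 5.42 ± 0.33 to 10.36 ± 0.16 (SD, n = 3 per group; adjusted p = 1.13e-05 by limma). The fatty acid elongase Elovl7 rose 13.3-fold, the surface antigen Ly6d 10.8-fold, the tubulin Tubb2a 10.3-fold and the glycoprotein Gpnmb 10.2-fold. Pnldc1 rose 8.76-fold, the glycerol channel Aqp7 8.19-fold, Tmem154 8.1-fold and the leptin receptor Lepr 7.74-fold. The lipid droplet protein Cidec rose 7.03-fold, Cgref1 6.05-fold and Fgf21, a hormone the liver secretes during fasting, 5.98-fold. The largest decrease was that of Cyp7a1, the rate-limiting enzyme of bile acid synthesis, which was 16.1-fold lower (log2 9.22 ± 0.11 in controls and 5.21 ± 0.73 in knockouts, SD, n = 3 per group; adjusted p = 0.000255 by limma). The transporter Slc22a30 was 12.2-fold lower, the bile acid and steroid reductase Akr1d1 11.7-fold, the corticosteroid-binding globulin gene Serpina6 10.2-fold and the serum amyloid gene Saa4 8.76-fold. Apol7a was 8.69-fold lower, the aldehyde oxidase Aox3 8.53-fold, the aldo-keto reductases Akr1c20 and Akr1c6 8.33-fold and 7.41-fold, and the mitochondrial carbonic anhydrase Car5a 6.92-fold. The methyltransferase Inmt was 6.5-fold lower and the amino acid transporter subunit Slc3a1 6.32-fold.

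Adjusted p for these 24 genes ran from 1.13e-05 to 0.00451, the highest being that of Lepr, whose knockout values of 5.96, 8.02 and 7.03 spread most widely. Lepr (adjusted p = 0.0929) and Akr1c6 (0.0521) lost the call with every probe set tested. With unmoderated statistics Lepr, Akr1c6, Akr1c20 and Tmem154 lost it, and with listed age as a covariate Lepr, Slc3a1, Pnldc1 and Cyp7a1. Tubb2a, Slc22a30, Apol7a, Saa4 and the Akr1c genes have close relatives in the genome, whose RNA can bind the same probes. Control values of Elovl7 (2.56) and Tmem154 (2.55) lay below the median of all probe sets, 2.88, a range in which RMA understates folds.

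**Figure D1:**
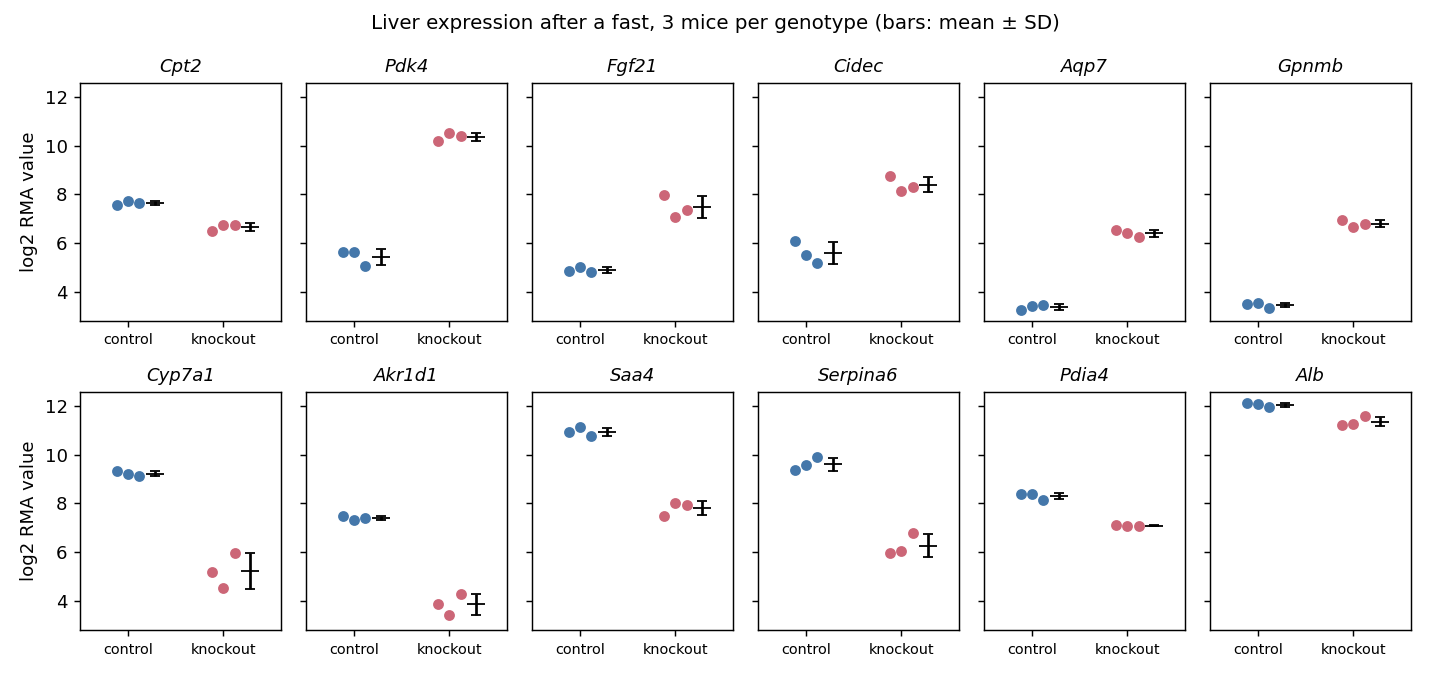
Deposited log2 RMA values of 12 genes in each of the 3 control and 3 knockout livers (points), with the mean and SD of each group (bars). In each panel the knockout points lie on 1 side of all control points, from Pdk4, 30.5-fold higher, to Cyp7a1, 16.1-fold lower.

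Over all genes, 1667 of 20242 changed (8.24%), of which 960 were higher and 707 lower in the knockouts. In 392 of them the change was at least 2-fold, 194 upward and 198 downward, and in 62 it was at least 4-fold, 29 upward and 33 downward. The groups did not overlap in any of the 1667 changed genes, and in 25.1% of all genes tested, where chance gives 10%. The count was 1036 without control replicate 2 and 1059 without control replicate 3, 367 with every probe set tested, 652 with unmoderated statistics and 83 with listed age as a covariate, and the count of changes of at least 2-fold was 216 and 83 in the last 2 of these.

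Of the 39 gene lists tested by camera, 10 were higher and 10 lower at adjusted p under 0.05 with the preset correlation. With an estimated correlation 0 lists passed (14 at an unadjusted p under 0.05, smallest adjusted p = 0.0646), and by fry 19 did, 17 of them among the 20. A higher correlation is not the whole reason for the lost calls. The test with an estimated correlation rests on 4 residual degrees of freedom. For lipid droplet proteins the estimate was -0.00643, under the preset 0.01, yet the unadjusted p by camera went from 3.97e-12 to 0.00166. Estimates were also under the preset for the ketone body (-0.193), thioesterase (-0.018), p53 (-0.0353) and female liver (-0.0635) lists. Their unadjusted p by camera went from 0.00505, 0.00481, 0.000371 and 0.00431 to 0.0459, 0.0422, 0.0188 and 0.0413. The adjusted p-values with an estimated correlation below thus do not measure correlation between genes alone. Median, mean and test had the same sign in each of the 20.

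By camera, lists of lipid handling genes were higher. Of 29 measured targets of PPARA, the fatty acid receptor that drives the fasting response, 18 rose (19 adjusted over the list alone) and 11 did not pass, with a median log2 fold change of 0.70 (adjusted p = 3.63e-20 by camera, adjusted p = 0.0663 with an estimated correlation). Pdk4, Aqp7, Cidec and Fgf21 led the list. Among 19 lipid droplet proteins, 12 rose (12 adjusted over the list alone) and the median was 0.69 (adjusted p = 2.21e-11, and adjusted p = 0.0646 with an estimated correlation). Beside Cidec these included Plin4 (log2 fold change 2.08), Hilpda (1.74) and Plin2 (1.18). The droplet list shares 9 measured genes with the PPARA list. Of 18 genes of fatty acid uptake and activation, 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them the fatty acid transporters Cd36 (1.58) and Slc27a1 (1.08) and the binding protein Fabp2 (1.04). The member that fell was Slc27a5 (-0.76), which also activates bile acids. The list had adjusted p = 9.66e-05, and adjusted p = 0.116 with an estimated correlation.

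In the peroxisomal list, 4 of 14 rose and 1 fell (6 and 2 adjusted over the list alone), with Pex11a at 1.54, Ehhadh at 1.32 and Crat at 0.86 on the log2 scale against -1.41 for Pecr (adjusted p = 0.00151, adjusted p = 0.455 with an estimated correlation, 0.067 by fry, 0.978 with listed age). In the mitochondrial list, 3 of 16 genes rose (5 adjusted over the list alone), Decr1 by 0.43, Etfdh by 0.39 and Hadhb by 0.37, with a list median of 0.21 (adjusted p = 0.028, adjusted p = 0.543 with an estimated correlation, 0.109 by fry). That list's adjusted p was also 0.0699 over genes above the 25th percentile of level, 0.142 over genes above the median level, 0.0878 with array weights and 0.881 with listed age (median 0.09). It was 0.0576 without control replicate 2, 0.0686 without control replicate 3 and 0.217 without knockout replicate 3, and Etfdh and Hadhb passed in none of the 6 fits that left out an array and Decr1 in 1. Of 10 acyl-CoA thioesterases, 3 rose and 1 fell (4 and 1 adjusted over the list alone), Acot2 (2.14) and Acot6 (1.30) most (adjusted p = 0.0104, adjusted p = 0.129 with an estimated correlation, 0.0912 over genes above the median level, 0.368 with listed age). The ketone body list also passed (adjusted p = 0.0104, adjusted p = 0.129 with an estimated correlation, 0.0641 without knockout replicate 3, 0.201 with listed age, where its median was 0.01). Its 2 members that rose of 5 measured (2 adjusted over the list alone) were the monocarboxylate transporters Slc16a6 (0.95) and Slc16a1 (0.80). Slc16a6 had an adjusted p of 0.054 without control replicate 2 and 0.0527 without control replicate 3. The omega oxidation list did not pass by camera (adjusted p = 0.338, 0.0386 by fry). In it Aldh3a2 (1.03) and Adh7 (0.77) rose while Cyp4f14 (-1.83) and Adh4 (-1.28) fell, in all 2 up and 3 down of 6 (2 and 3 adjusted over the list alone).

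Of 16 measured genes of bile acid synthesis and transport, 12 fell (13 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.87 (adjusted p = 2.51e-13, adjusted p = 0.0663 with an estimated correlation). After Cyp7a1 (-4.01) and Akr1d1 (-3.55), the largest were the bile salt export pump Abcb11 (-2.35) and the nuclear receptor Nr0b2 (-1.90). In the cholesterol synthesis list, 4 of 19 fell and 1 rose (7 and 1 adjusted over the list alone), with Ebp at -0.93 and a median of -0.34 (adjusted p = 0.00193, adjusted p = 0.358 with an estimated correlation, 0.067 by fry). The others that fell, Msmo1, Fdft1 and Sc5d, lost the call without control replicate 1 (adjusted p = 0.0563, 0.133 and 0.0514 by limma). They also lost it without control replicate 3 (0.0504, 0.15 and 0.0633). Fatty acid synthesis was split, with 4 of 17 genes higher and 5 lower (4 and 8 adjusted over the list alone). Thrsp (-1.86) and Scd1 (-1.43) fell, and Acacb (1.45) and Elovl5 (0.90) rose (adjusted p = 0.154 for the list, 0.0377 without control replicate 2, 0.0324 with listed age, where its median was -0.25).

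By camera with the preset correlation, lists of amino acid catabolism, the urea cycle and xenobiotic metabolism were lower as well. Of 25 genes of amino acid catabolism, 11 fell (17 adjusted over the list alone), led by the histidase gene Hal (-1.73), Kynu (-1.34), Haao (-1.10) and Prodh (-1.05), with a median of -0.53 (adjusted p = 1.43e-13, adjusted p = 0.0663 with an estimated correlation). In the urea cycle, Otc (-0.99) and Nags (-0.69) fell of 7 measured (4 adjusted over the list alone; adjusted p = 7.06e-05, adjusted p = 0.129 with an estimated correlation). Of 11 genes of xenobiotic metabolism, 4 fell (5 fell and 1 rose adjusted over the list alone), the sulfotransferases Sult1d1 (-2.18) and Sult1a1 (-1.15) and the cytochromes Cyp3a13 (-1.67) and Cyp1a2 (-1.06), with adjusted p = 6.23e-05 for the list and adjusted p = 0.144 with an estimated correlation. Genes higher in male liver fell, 6 of 11 (6 adjusted over the list alone), with Slco1a1 at -1.78 on the log2 scale (adjusted p = 7.06e-05, adjusted p = 0.129 with an estimated correlation). The list of genes higher in female liver was lower too (adjusted p = 0.00989, adjusted p = 0.129 with an estimated correlation), although 1 of its 9 members, Cyp3a16 (-0.45), passed (2 adjusted over the list alone). Cyp3a16 passed in 1 of the 6 fits that left out an array.

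Stress responses went both ways. Of 25 genes of the integrated stress response, which acts through the transcription factor ATF4, 14 rose (16 adjusted over the list alone), with a median of 0.62 (adjusted p = 5.63e-12, adjusted p = 0.0663 with an estimated correlation). Fgf21 (2.58), Atf3 (2.42), Nupr1 (1.43) and the serine synthesis gene Psat1 (1.33) led it. Genes of the endoplasmic reticulum unfolded protein response list fell, 13 of 18 (15 adjusted over the list alone), with a median of -0.72 (adjusted p = 1.43e-13, adjusted p = 0.107 with an estimated correlation). Sdf2l1 (-1.25), Pdia4 (-1.21), Derl3 (-1.14) and Dnajb11 (-1.03) fell most. Among 20 targets of NRF2, the regulator of antioxidant genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with Cbr3 (2.23), Srxn1 (1.34), Ugdh (1.32) and Pgd (1.27) highest (adjusted p = 0.000764, adjusted p = 0.3 with an estimated correlation). With listed age as a covariate the list's median turned from 0.24 to -0.08 and it did not pass (adjusted p = 0.248). Of 16 p53 targets and growth arrest genes, 4 rose (7 adjusted over the list alone), Cdkn1a by 1.95, Btg2 by 1.47 and Tnfrsf10b by 1.03 on the log2 scale (adjusted p = 0.00103, adjusted p = 0.105 with an estimated correlation). The mitochondrial chaperone list had adjusted p = 0.0517, with 1 of 11 genes higher (2 adjusted over the list alone). The list passed with every probe set (0.0164) and without control replicate 1 (0.0323), knockout replicate 1 (0.0322) or knockout replicate 2 (0.014). Its 1 higher gene, Lonp1 (0.36), passed in none of the 6 fits that left out an array.

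Of 20 genes in the acute phase and complement list, 11 fell (13 fell and 1 rose adjusted over the list alone), with a median of -0.80 (adjusted p = 1.65e-11, adjusted p = 0.13 with an estimated correlation). With listed age as a covariate the list's median was -0.22 (95% interval -0.53 to 0.40; adjusted p = 0.0492 by camera, 0.341 by fry). Saa4 (-3.13) was followed by Saa3 (-2.06), the fibrinogen chain Fgg (-1.34) and the complement gene C9 (-1.03). Saa3 lost the call without control replicate 2 (adjusted p = 0.0503), knockout replicate 2 (0.0556) or knockout replicate 3 (0.0658), with every probe set tested, with unmoderated statistics and with listed age as a covariate. Hepatocyte markers were also lower, 7 of 13 (10 adjusted over the list alone), with Vtn at -0.77, Alb at -0.69 and Kng1 at -0.66 and a list median of -0.53 (adjusted p = 3.32e-09, adjusted p = 0.105 with an estimated correlation). Lists of secreted factors and apolipoproteins did not pass (adjusted p = 0.154 and 0.339). Of 19 secreted factors, 4 rose and 6 fell (5 and 7 adjusted over the list alone), including Inhbe (1.59) beside Fgf21 and Enho (-1.19), and the list had adjusted p = 0.0409 without knockout replicate 3. Of 13 genes of lipoprotein secretion, 2 rose and 2 fell (3 and 2 adjusted over the list alone), among them Apoa4 (0.76) and Apom (-0.85).

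Lists of central carbon metabolism, cell cycle, autophagy and clock genes did not pass by camera on the deposited values of 20242 genes in all 6 arrays, without a covariate. In gluconeogenesis (adjusted p = 0.339), Fbp1 (-0.94), Slc37a4 (-0.67) and Gpt (-0.61) fell and Pck2 (0.87) rose of 12 measured (2 up and 4 down adjusted over the list alone). Glycolysis (adjusted p = 0.76) had 1 gene up, Aldoa (0.83), and 1 down of 13 (1 and 3 adjusted over the list alone). In the citric acid cycle list (adjusted p = 0.243) 2 of 17 rose (2 adjusted over the list alone), with Cs at 0.62. Oxidative phosphorylation (adjusted p = 0.711, 0.0287 without knockout replicate 3, with a median of -0.11, and 0.0133 with listed age, with a median of -0.21) had 1 of 32 genes up (1 adjusted over the list alone). The cell cycle list (adjusted p = 0.76) had 1 of 24 genes up (1 adjusted over the list alone). Autophagy and lysosome genes (adjusted p = 0.0894, 0.0162 by fry, 0.0474 after quantile normalization, 0.0191 with every probe set, 0.0323 without control replicate 1 and 0.0448 without knockout replicate 2) had 3 up and 1 down of 17 (4 and 2 adjusted over the list alone), with Sqstm1 at 1.08 and Lipa at 0.91. Of 16 clock genes (adjusted p = 0.431), 1 rose and 4 fell (3 and 5 adjusted over the list alone), among the latter Hlf (-0.91) and Tef (-0.75). The others that fell, Per3 and Ciart, both lost the call without control replicate 1 (adjusted p = 0.0731 and 0.12 by limma). The same held without knockout replicate 1 (0.0539 and 0.122) or knockout replicate 2 (0.0717 and 0.128).

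Marker lists of other cell types did not pass by camera in the fit of all 6 arrays without a covariate. The macrophage list had 3 genes up and 1 down of 16 (3 and 2 adjusted over the list alone; adjusted p = 0.421, median -0.20), with Gpnmb (3.35), Cd68 (2.32) and Cd14 (1.09) higher. With listed age as a covariate its median turned to 0.15 and it passed (adjusted p = 0.00346). Krt23 (1.91) was the 1 of 7 cholangiocyte markers that rose (1 adjusted over the list alone; adjusted p = 0.818), and Lyve1 (0.92) the 1 of 12 endothelial markers (1 adjusted over the list alone; adjusted p = 0.841). Of 15 stellate cell, 13 lymphocyte, 11 neutrophil and 3 erythrocyte markers 0 passed in limma, over all genes, over the list alone or at an unadjusted p under 0.05, and the lists had adjusted p = 0.818, 0.281 and 0.174, with erythrocyte markers too few to test. Their largest changes were 0.31 for Ccn2, -0.24 for Cd3g, -0.27 for Csf3r and -0.31 for Alas2. Of 10 adipocyte and pancreas markers, Car3 (-2.17), which male liver also expresses, fell (1 adjusted over the list alone; adjusted p = 0.154, 0.0434 without control replicate 1 and 0.0461 without knockout replicate 2).

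**Figure D2:**
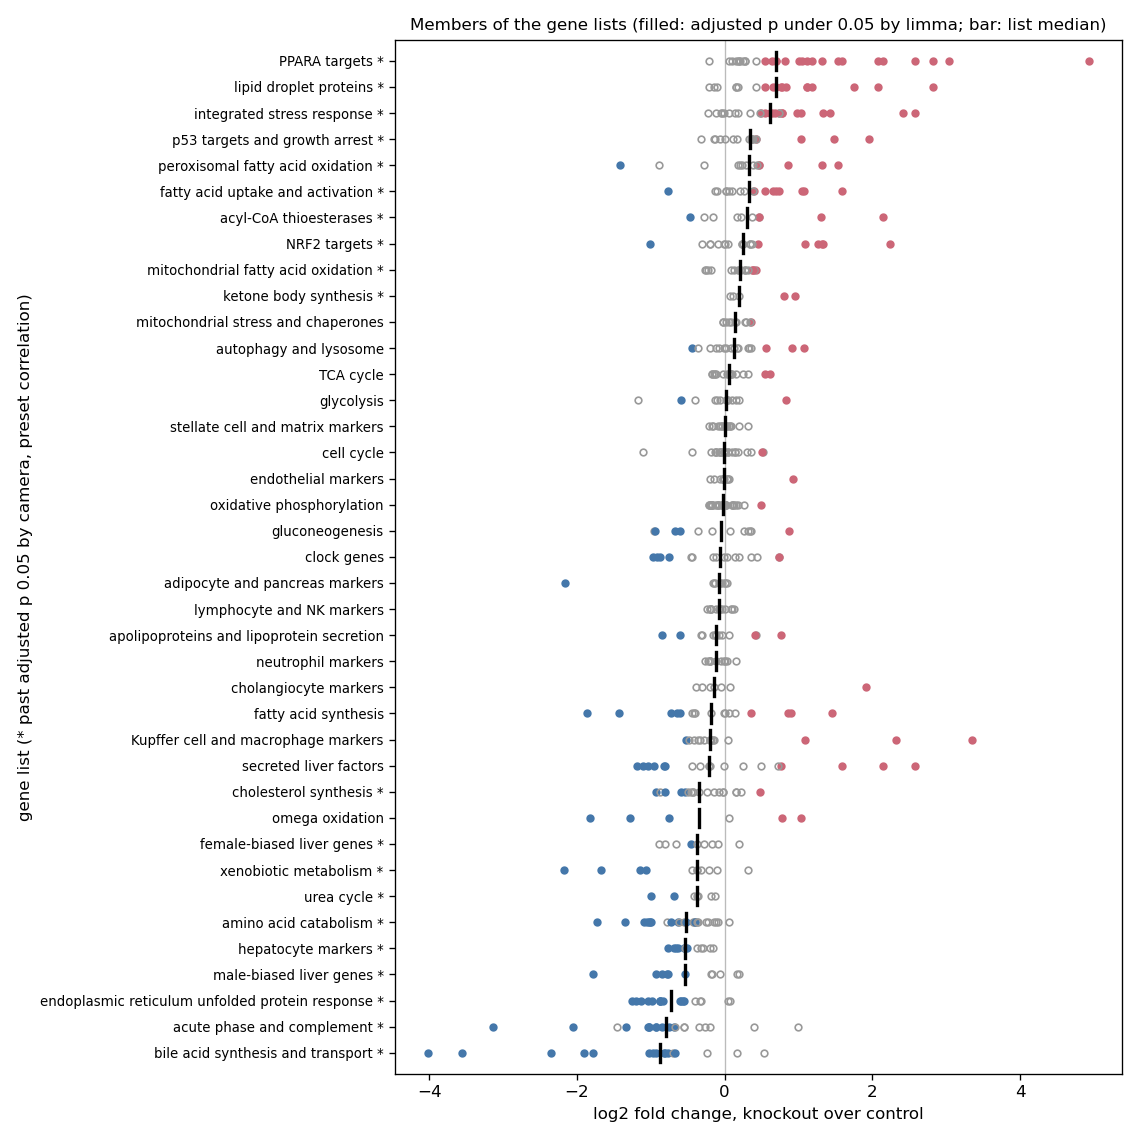
Log2 fold change (knockout over control) of each measured member of the 39 tested gene lists, ordered by list median (black bar). Filled points passed adjusted p 0.05 in limma, red higher and blue lower in knockouts. PPARA targets (median 0.70) stand at the top and bile acid genes (median -0.87) at the bottom.

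The listed ages were compared within genotype, since the labels list controls at 9 to 11 weeks and knockouts at 12 to 14 weeks. By limma, 0 of 20242 genes changed with listed age (768 at an unadjusted p under 0.05, where chance gives 1012, smallest adjusted p = 0.581). With listed age as a covariate, 391 of the 392 genes changed at least 2-fold kept the direction of their difference between genotypes. Listed age and genotype do not overlap, and the covariate raised the SE by a median factor of 2.21. Within each genotype listed age rises with the replicate number, so these fits cannot tell age from sample order.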

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

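The tests of the hepatocyte share and of macrophage number, and fry and the estimated correlation with listed age as a covariate, were chosen after the fold changes they use were seen. Probe sets outside the gene comparison also differed between the genotypes when every probe set was tested together by limma. Of those naming several genes, 9 were higher and 19 lower in knockouts at adjusted p under 0.05, and of those naming no gene in the annotation, 44 were higher and 84 lower. Among the former, probe set 6837818 had a log2 fold change of 3.16 (adjusted p = 0.0057) and 6873064 of -2.97 (adjusted p = 0.00935). Among the latter, probe set 6806081 had 3.82 (adjusted p = 0.0146) and 6753988 -4.73 (adjusted p = 0.00162). No gene is named for them here.

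The lists of hepatocyte markers, acute phase genes and unfolded protein response genes were lower by camera, with a median log2 fold change of -0.63 over their 51 genes, of which 7 of 13, 11 of 20 and 13 of 18 fell (adjusted p = 0.105, 0.13 and 0.107 with an estimated correlation). A lower share of hepatocyte RNA would raise the markers of other liver cells. Over 41 macrophage, stellate, cholangiocyte, endothelial and lymphocyte markers above the median level, the median was -0.0279 (95% interval over genes -0.19 to 0.03). Without a covariate, this argues against a lower share as the whole cause. With listed age as a covariate the macrophage list was higher by camera with the preset correlation (adjusted p = 0.00346). Its median was 0.15 (95% interval over genes -0.06 to 0.82), and the 41 markers were not refitted. A trend with brightness is argued against by 10000 random lists matched on mean expression, whose medians had a median of 0.0368 and ran from -0.24 to 0.19. A change within hepatocytes that lowers genes of the secretory pathway is a candidate explanation that these values leave open. Not all lists of secreted products were lower. Secreted factors had 4 genes up and 6 down of 19, and lipoprotein secretion 2 up and 2 down of 13. Neither list passed by camera (adjusted p = 0.154 and 0.339). A difference in age stays open too, as listed age does not overlap between the genotypes. With it as a covariate the median was -0.54 for hepatocyte markers (adjusted p = 1.64e-06 by camera, adjusted p = 0.279 with an estimated correlation, 0.0706 by fry). It was -0.72 for unfolded protein response genes (6.79e-09, 0.279 and 0.105) and -0.22 for acute phase genes (0.0492, 0.602 and 0.341). By limma 0, 0 and 1 genes of these lists were lower.

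Gpnmb, Cd68 and Cd14 rose while the other macrophage markers did not. More macrophages of the kind the markers describe would raise them all. The 16 markers had a median of -0.20 (95% interval over genes -0.36 to 0.05), with 3 higher and 1 lower by limma. The upper bound was set against the 1.09 of Cd14, the smallest of the 3 rises. That comparison cannot decide, since such a bound for 16 values lies below their 3 highest whatever the data. With listed age as a covariate the median was 0.15 (95% interval -0.06 to 0.82; adjusted p = 0.00346 by camera) while Cd14 lost its call (1.56, SE 0.36, adjusted p = 0.148 by limma), so whether the markers as a group were higher depends on that covariate. More macrophages, a macrophage subtype that the list describes poorly, or expression in hepatocytes, all stay open. Whether lysosomal genes rose in general cannot be settled, since the median of 39 of them was 0.0547 (95% interval -0.08 to 0.27), with adjusted p = 0.117 by limma's camera.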

How the results depend on the processing

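All 1667 genes kept their direction in each setting that held them, except 5 with the mean of all probe sets (1662 kept) and 3 with listed age as a covariate (1664 kept). Direction could turn only in these settings, with quantile normalization or with centring. In the others the fold change was the same, or non-overlapping groups fixed its sign. The count moved from 1667 to 367 with every probe set tested, of which 189 were shared, to 652 with unmoderated statistics (585 shared) and to 83 with listed age as a covariate (79 shared). It ranged from 1036 to 1305 when 1 array was left out, lowest without control replicate 2 (1036) and control replicate 3 (1059). The count of changes of at least 2-fold was 216 with unmoderated statistics and 83 with listed age, and 377 to 410 without 1 array. Testing every probe set changes both the adjustment and the moderated variances, and unadjusted p was under 0.05 for 3012 of 25469 probe sets naming 1 gene, against 4083 of 20242 genes. Unmoderated statistics have fewer degrees of freedom and listed age raised the SE. Genes higher in knockouts were 57.6% of calls, 55.1% after quantile normalization and 57.8% after centring, and 42.2% with listed age, the cause of which was not tested. With every probe set they were 42.8% of calls, which count probe sets, and 49.3% (104 up, 107 down) of those naming 1 gene; probe sets naming no gene (44 up, 84 down) or several (9 up, 19 down) lower the share. Cpt2 had a log2 fold change of -0.99 with adjusted p = 0.0692 with every probe set, -1.24 with adjusted p = 0.0753 with listed age, and -1.03 to -0.90 without 1 array. Passing lists numbered 0 with an estimated correlation, 19 by fry, 17 to 22 under the other settings, and 19 to 23 without 1 array. The macrophage list, not called otherwise, had a median of 0.15 with listed age (adjusted p = 0.00346 by camera with the preset correlation), against -0.20. The cause was not tested. With listed age the peroxisomal, mitochondrial, ketone body, thioesterase and NRF2 lists lost the call and the fatty acid synthesis and oxidative phosphorylation lists gained it. Replicate number as a block gave 1384 genes, 1295 of them shared, and ended the call of the mitochondrial fatty acid oxidation list (adjusted p = 0.0525). Deviations of same-numbered samples correlated at 0.07, 0.18 and -0.08, and not every sample correlated best with its own number. With 3 samples per group these values cannot tell whether same-numbered samples were paired. Of 131 named genes beside Cpt2, 0 reversed in any setting, though for called genes most settings could not turn the direction. The call was lost by 77 with every probe set, 61 with unmoderated statistics, 97 with listed age and 28 in at least 1 fit without 1 array. No signal over background was used here, so what dim genes can show stays open.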

Other observations

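All gene families in this part were grouped by symbol after the data were seen, 724 families of 5 to 60 genes, of which 19 were higher and 21 lower at adjusted p under 0.05 by camera with the preset correlation. Some families are parts of others, such as Ces1 and Ces2 within Ces, so these counts are not of separate gene sets. With an estimated correlation 0 families passed (smallest adjusted p = 0.852). That test rests on 4 residual degrees of freedom and is adjusted over 724 families, so it had little power here. For the Ces family the unadjusted p by camera went from 2.79e-09 to 0.00331. The adjusted p-values with an estimated correlation below are thus no measure of correlation between genes. Members are named here after their values were seen, and the median of each family named here kept its sign under quantile normalization and centring. Carboxylesterases, which hydrolyse lipid esters and drugs, were lower, with 6 of 12 past the gene threshold, Ces1g (-1.45) and Ces3b (-1.17) most, and a family median of -0.65 (adjusted p = 6.73e-07 by camera, adjusted p = 0.852 with an estimated correlation). Carbonic anhydrases fell in 6 of 16 members and rose in 1. Beside Car5a these were Car14 (-2.54), Car3 (-2.17), Car1 (-2.06), Car8 (-1.66) and Car5b (-0.86), against Car2 (0.68), with adjusted p = 0.00041 for the family and adjusted p = 0.852 with an estimated correlation. Of 6 Slco1 organic anion transporters 4 fell, Slco1a4 most (-2.47), with adjusted p = 8.19e-05 and adjusted p = 0.852 with an estimated correlation. Close relatives in each of these families can share probe signal.

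Among families that were higher, 5 of 8 beta-tubulins rose, Tubb2a (3.37), Tubb2b (1.42) and Tubb6 (1.26) most, with a median of 0.66 (adjusted p = 0.000223, adjusted p = 0.999 with an estimated correlation). In the Rrp family 3 of 8 genes rose, with Rrp12 at 0.76, in the Nop family 3 of 8, with Nop2 at 0.80, and in the Utp family 4 of 10, with Utp14a at 0.61 (adjusted p = 0.00231, 0.0359 and 0.0189, each 0.999 adjusted p with an estimated correlation). Of 13 Psmd subunits of the proteasome, 3 rose, with Psmd8 at 0.94 (adjusted p = 0.000562, adjusted p = 0.999 with an estimated correlation).

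Of 13 Snhg genes, hosts of small nucleolar RNAs, 7 rose, with a family median of 0.42, led by Snhg10 (1.39) and Snhg1 (1.01; adjusted p = 0.000223 for the family, adjusted p = 0.852 with an estimated correlation). A brightness trend is argued against, since matched random lists had a median of 0.000303 and ran from -0.27 to 0.30. Slower nonsense-mediated decay, which degrades Snhg transcripts, stays open, as the 7 measured decay factors had a median of 0.0644 (95% interval -0.13 to 0.51), with adjusted p = 0.102 by limma's camera. A general rise of transcripts with the same kind of start sequence may contribute. Over 64 ribosomal protein genes, of which 2 rose by limma, the median was 0.11 (95% interval over genes 0.07 to 0.15). The list had adjusted p = 0.00947 by camera and unadjusted p = 0.207 with an estimated correlation. Its median is well below that of the Snhg genes.

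For the count of 1667 changed genes, 1 of the 10 splits of the 6 samples into groups of 3 gave as many, the real one, and the highest of the others gave 0. The 10 splits are too few for a share under 0.05.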
